A study of Mus musculus with 36 samples.

How the data were processed

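RNA from 36 mouse livers was hybridised to an Affymetrix whole-transcript mouse gene array, 1 liver per array, after biotin labelling. Per the labels, the mice were littermates with a liver-specific knockout of Cyp51 (LKO) or without it (LWT), of both sexes. From weaning at 3 weeks of age they ate 1 of 3 diets for 16 weeks, and livers were taken after a 5 h fast. The diets were a standard chow with little fat and no cholesterol (LFnC), a diet rich in fat but free of cholesterol (HFnC) and one rich in fat that held cholesterol at 1.25% by weight (HFC). Per the labels 136 mice were fed in all, and 36 of them are on these arrays, 3 in each of 12 groups. The chow comes from another supplier than the high-fat diets, so the comparison of HFnC with LFnC covers every difference between those feeds and not fat alone. The labels also give a batch of 1 to 3, which equals the replicate number within each group.

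The deposited values are on the log2 scale and, per the submitters' processing notes, come from RMA. The version of RMA, the annotation it used and any batch correction are not given in the sources used here. Of 35556 rows, 9856 were empty on every array and none was empty on only some arrays. The rule behind the empty rows is not given in the sources used here. Values ran from 3.04 to 14.4, array medians from 7.45 to 7.59, and correlations between arrays from 0.966 to 0.997, and no pair of arrays was identical. For arrays the number of mice, not a count of reads, limits the precision.

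Of the 25700 rows with values, 20781 carried 1 gene symbol in the probe table, 235 carried several and 4684 were not listed there. Each gene was represented by its row with the highest mean over all arrays, which mattered for 565 genes and left 19664 genes. For 19587 of them the gene number of the probe table matched the reference table, and the other 77 kept the probe table's symbol. Rows with several symbols or none were left out of the comparisons and counted separately in the closing section. Probe sets of near-identical genes (Cyp4a12a and Cyp4a12b, Saa1 and Saa2, Sult3a1 and Sult3a2, Orm2 and Orm3, Cyp2b9 and Cyp2b13, Mup21) may read each other's transcripts, so each such name stands for its probe set.

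All 36 arrays were fitted in 1 linear model with a mean for each of the 12 groups in limma 3.58.1 under R 4.3.3, with plain empirical Bayes moderation. Contrasts of the group means gave 17 comparisons: the genotype (LKO minus LWT) over all diets and both sexes, in each sex and on each diet; fat (HFnC minus LFnC) and cholesterol (HFC minus HFnC) in each genotype; sex (female minus male) in each genotype; and 5 differences of differences. Each contrast weighs the groups it averages equally. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 19664 genes. SE is the moderated standard error of a log2 change, and SD the spread between the 3 mice of a group.

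The lists of genes, 28 in all, were fixed before the data were examined, as were the comparisons, the threshold and most of the other settings tried. They cover cholesterol synthesis, sterol-responsive genes outside the pathway, LXR targets, bile acid synthesis, bile acid transport and FXR targets, fatty acid and triglyceride synthesis, PPARalpha targets and fatty acid oxidation, and lipid droplet and fatty acid uptake. Further lists hold gluconeogenesis and insulin response, CAR and PXR targets, NRF2 targets, endoplasmic reticulum stress, the acute phase, cell division, the circadian clock, immediate early and heat shock genes, and male-biased and female-biased liver genes. The cell type lists hold hepatocyte markers, cholangiocyte and ductular cell markers, stellate cell, fibroblast and matrix genes, macrophage and Kupffer cell markers, T, B and NK cell markers, neutrophil markers, liver endothelial markers, erythroid genes, pancreatic acinar genes and adipocyte genes. Of 346 list members 306 were measured. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with the adjustment over the 28 lists within a comparison, and again with an estimated correlation. Of 476 tests 173 were called at the preset correlation and 18 with the estimated one. Lists called over all arrays are given with both, and lists not called, or tested with arrays left out, with the preset one only. The level of a list on an array is the mean over its members of the log2 value minus the gene's mean over all arrays.

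The genes named were chosen by a fixed rule: Cyp51 and the genes used to check sex, then among called genes those with the largest changes. The rule took 6 up and 6 down for the genotype over all mice, the genotype by sex, fat, cholesterol and sex within each genotype, and 3 up and 3 down for the rest. Up to 4 members per list with the smallest p were added. Predicted genes, clone names, small RNAs, olfactory and vomeronasal receptors, mitochondrial genes and pseudogenes were not named.

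The fit was tested on simulated data with the same 12 groups and 19664 genes, with 50 genes changed at each size. Each simulated value was drawn independently from a normal distribution, without correlation between genes or outlying mice. The shares recovered and the false calls thus need not hold for the real arrays. For the genotype over all mice 100% of genes with a log2 change of 0.5 were recovered and 18 of 19464 unchanged genes were called. For the genotype on LFnC 94% were recovered at 0.5 and at 1 and 100% above, with 14 false calls. For the genotype by sex 78% were recovered at 0.5 and 100% from 1 upwards, with 6 false calls.

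The labels number the mice by batch across groups. Deviations from the group mean correlated at a mean of 0.0226 between arrays with the same number (from -0.419 to 0.624) and -0.0112 between other arrays, and 15 of 36 arrays correlated best with their own number. The median F for the batch over genes was 0.751, where 0.715 is the median with no batch effect. The batch was therefore left out of the model and used as a block in an alternative. Other settings removed the 40% of genes with the lowest mean, applied quantile normalisation or centred each array on its median, used trend and robust moderation, averaged a gene's probe sets, weighted the arrays, fitted only the groups of a comparison, or left out each array and each batch in turn. Later additions, chosen after seeing the data, left out a pair of male LWT arrays on HFC and used the level of the acinar list as a covariate. No column of values was left unused, and no genome sequence or genomic coordinates were used here.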

Results

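Liver gene expression was measured in 36 mice that differed in diet, sex and in whether the liver lacked Cyp51, the lanosterol 14-alpha-demethylase of cholesterol synthesis. Each of the 12 groups held 3 mice, so a comparison of genotypes within a diet set 6 LKO mice against 6 LWT mice, and the comparison over all diets set 18 against 18. The study's title names the effect of dietary fat and cholesterol on this knockout in both sexes. The values are log2 array intensities, and changes are given on that scale.

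Cyp51 itself was lower in LKO livers on every diet. On LFnC it read 8.44 to 9.38 in the 6 LKO mice and 9.68 to 10.5 in the 6 LWT mice, on HFnC 8.63 to 9.82 against 10.5 to 11.5, and on HFC 6.35 to 7.12 against 7.50 to 8.92. No LKO value overlapped an LWT value on the same diet. Whether the array's probes lie inside the deleted part of the gene is not known here. Xist, which is expressed from the inactive X chromosome, read 12.8 to 13.1 in the 18 females and 6.03 to 7.97 in the 18 males. The Y-linked Kdm5d, Eif2s3y and Uty read at most 6.33, 5.11 and 5.34 in females and at least 8.60, 9.87 and 9.36 in males, so no array contradicted its label.

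**Figure D1:**
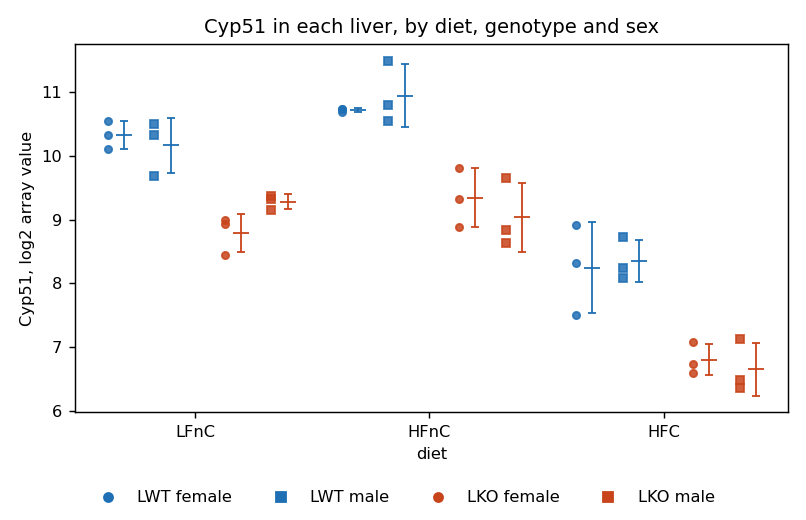
Cyp51 (log2 array value, vertical axis) in each liver by diet (horizontal axis), genotype (colour) and sex (marker); bars are the mean and SD of 3 mice. All 6 LKO livers lie below all 6 LWT livers on each diet, and on HFC both genotypes read lower, 6.35 to 7.12 in LKO and 7.50 to 8.92 in LWT.

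On the chow diet, LFnC, loss of Cyp51 came with higher expression of matrix, bile duct and macrophage genes and of other enzymes of cholesterol synthesis. No list was called on LFnC with an estimated correlation. Gpnmb, a transmembrane glycoprotein found in macrophages, rose from a mean of 6.68 (SD 0.30, n = 3) in LWT females to 10.43 (SD 0.69, n = 3) in LKO females, and from 6.43 to 9.99 in males. Its log2 change over both sexes was 3.66 (SE 0.69, adjusted p = 0.00033). Mmp12, the macrophage elastase, rose by 3.58 (SE 0.59, adjusted p = 9.5e-05), and Elovl7, a fatty acid elongase, by 3.19 (SE 0.47, adjusted p = 3.7e-05). The largest falls among the named genes were in genes with higher levels in female liver: Sult3a1 with -3.03 (SE 0.89, adjusted p = 0.012), Sult3a2 with -2.44 (SE 0.57, adjusted p = 0.0025) and Cyp3a16 with -2.43 (SE 0.78, adjusted p = 0.02). These changes average over the sexes. Sult3a1 read 10.88 in LWT females (SD 0.41, n = 3) and 4.48 in LKO females, against 4.34 in LWT males and 4.68 in LKO males. Values this low lie near the bottom of the array's range, so the size of the fall is not exact. Cyp3a16 lost its call without female LKO replicate 1.

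The cholangiocyte and ductular cell markers rose as a list on LFnC, with 8 of 9 measured members higher and none lower, and 8 higher adjusted over the list alone. The median was 1.20 (adjusted p = 1.6e-07, or adjusted p = 0.3 with an estimated correlation). Examples are the chloride channel Cftr (2.11), the adhesion molecule Epcam (2.24), the transcription factor Sox9 (1.20) and Cd24a (2.24). Its median in the 3 batches was 1.09, 1.28 and 1.32. The stellate cell, fibroblast and matrix list had 12 of 16 members higher and none lower (12 adjusted over the list alone). Its median was 1.08 (adjusted p = 1e-09, or adjusted p = 0.3 with an estimated correlation) and 1.15, 0.80 and 1.33 within the batches. Among them Timp1, an inhibitor of matrix metalloproteinases, rose by 2.50, the collagen cross-linking enzyme Lox by 1.42, the growth factor receptor Pdgfrb by 1.26 and the filament protein Vim by 0.92. Of 16 macrophage and Kupffer cell markers 9 rose and 2 fell (10 and 2 adjusted over the list alone). Their median was 0.72 (adjusted p = 9.8e-06, or adjusted p = 0.3 with an estimated correlation) and 0.87, 0.63 and 0.62 by batch. Cd14, a coreceptor for endotoxin, rose by 2.05, the chemokine receptor Ccr2 by 2.00, lysozyme (Lyz2) by 1.39 and the integrin Itgam by 1.32.

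Enzymes of cholesterol synthesis other than Cyp51 rose on LFnC, averaged over the sexes. The mean level of the list went from -0.028 in LWT to 1.04 in LKO males, and from 0.122 to 0.275 in females, a difference between the sexes that was not tested on this diet alone. Of 15 measured members 10 were higher and none lower (12 adjusted over the list alone). The list had a median of 0.61 (adjusted p = 1.9e-06, or adjusted p = 0.39 with an estimated correlation) and 0.85, 0.49 and 0.50 within batches. Lss, which makes lanosterol, rose by 1.11, Hmgcs1 by 0.95, Mvk by 0.79 and Fdft1 by 0.57. The NRF2 targets, genes of antioxidant defence, had 5 of 8 members higher (6 adjusted over the list alone; median 0.45, adjusted p = 0.00053, or adjusted p = 0.3 with an estimated correlation), among them Gstm3 (1.61), Slc7a11 (1.55), Srxn1 (1.07) and Nqo1 (0.63). Acute phase genes had 6 of 15 higher (6 adjusted over the list alone; median 0.20, adjusted p = 0.0034, or adjusted p = 0.51 with an estimated correlation), with Lcn2 at 2.72, Saa2 at 1.44 and Orm2 at 1.32. Cell division genes had 3 of 13 higher (3 adjusted over the list alone; median 0.41, adjusted p = 0.0034, or adjusted p = 0.51 with an estimated correlation), namely Mki67 (0.90), Ccna2 (0.84) and Top2a (0.72). Neutrophil markers had 5 of 10 higher (5 higher and 1 lower adjusted over the list alone; median 0.28, adjusted p = 0.0046, or adjusted p = 0.3 with an estimated correlation), with Cxcr2 at 1.86 and Csf3r at 1.17. PPARalpha targets and genes of fatty acid oxidation fell, 10 of 14 lower and none higher (10 adjusted over the list alone; median -0.33, adjusted p = 0.0046, or adjusted p = 0.51 with an estimated correlation), such as Acaa1b (-0.73), Cpt2 (-0.46) and Acadl (-0.36). That list lost its call when batch 1 was left out.

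The other lists did not pass the test on LFnC, although single members did. For bile acid synthesis the median was -0.18 with 1 member of 12 higher and 4 lower (adjusted p = 0.18), and for gluconeogenesis and insulin response -0.26 with 6 of 10 lower (adjusted p = 0.059). Female-biased liver genes had a median of -1.13 with 4 of 10 lower (adjusted p = 0.1), and male-biased genes -0.23 with 2 of 13 higher and 2 lower (adjusted p = 0.84). Bile acid transport and FXR targets split, 3 of 13 higher and 3 lower (median -0.24, adjusted p = 0.91), with the transporter Slc51b at 1.23 and Slco1a1 at -1.38. CAR and PXR targets split as well, 2 of 7 higher and 3 lower (median 0.06 and mean -0.12, adjusted p = 0.84), with Cyp2c55 at 1.87 and Cyp2b10 at -2.15. LXR targets had a median of -0.09 and a mean of 0.12 (adjusted p = 0.84), with 1 of 10 higher, the lipase Lpl at 1.77, and 2 lower. Lipid droplet and fatty acid uptake genes had 2 of 12 higher, among them Cd36 (0.58), and 2 lower, among them G0s2 (-1.30), with a median of 0.18 (adjusted p = 0.31). The medians of sterol-responsive genes outside the pathway (0.10, adjusted p = 0.18), fatty acid and triglyceride synthesis (0.06, adjusted p = 0.73) and endoplasmic reticulum stress (-0.10, adjusted p = 0.73) were small. The circadian clock (-0.23, adjusted p = 0.36) and immediate early and heat shock genes (0.04, adjusted p = 0.18) also did not pass; in the latter list the called members were Jun (1.17) and Atf3 (1.05). Among cell types, hepatocyte markers had a median of -0.05 (adjusted p = 0.8), liver endothelial markers -0.03 (adjusted p = 0.84), T, B and NK cell markers 0.08 (adjusted p = 0.21), erythroid genes -0.28 (adjusted p = 0.14), adipocyte genes -0.27 (adjusted p = 0.18) and pancreatic acinar genes -0.51 (adjusted p = 0.84).

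In all, 6575 genes were called for the genotype on LFnC, 2787 higher and 3788 lower, of which 301 were at least 2-fold higher and 39 at least 2-fold lower. With each array centred on its median 9982 genes were called, 2226 of them higher (22.3%, against 42.4%), and with dim genes removed 4315, 2348 of them higher (54.4%). Which direction holds the majority thus depends on the setting. Without male LKO replicate 2 the count was 4090.

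**Figure D2:**
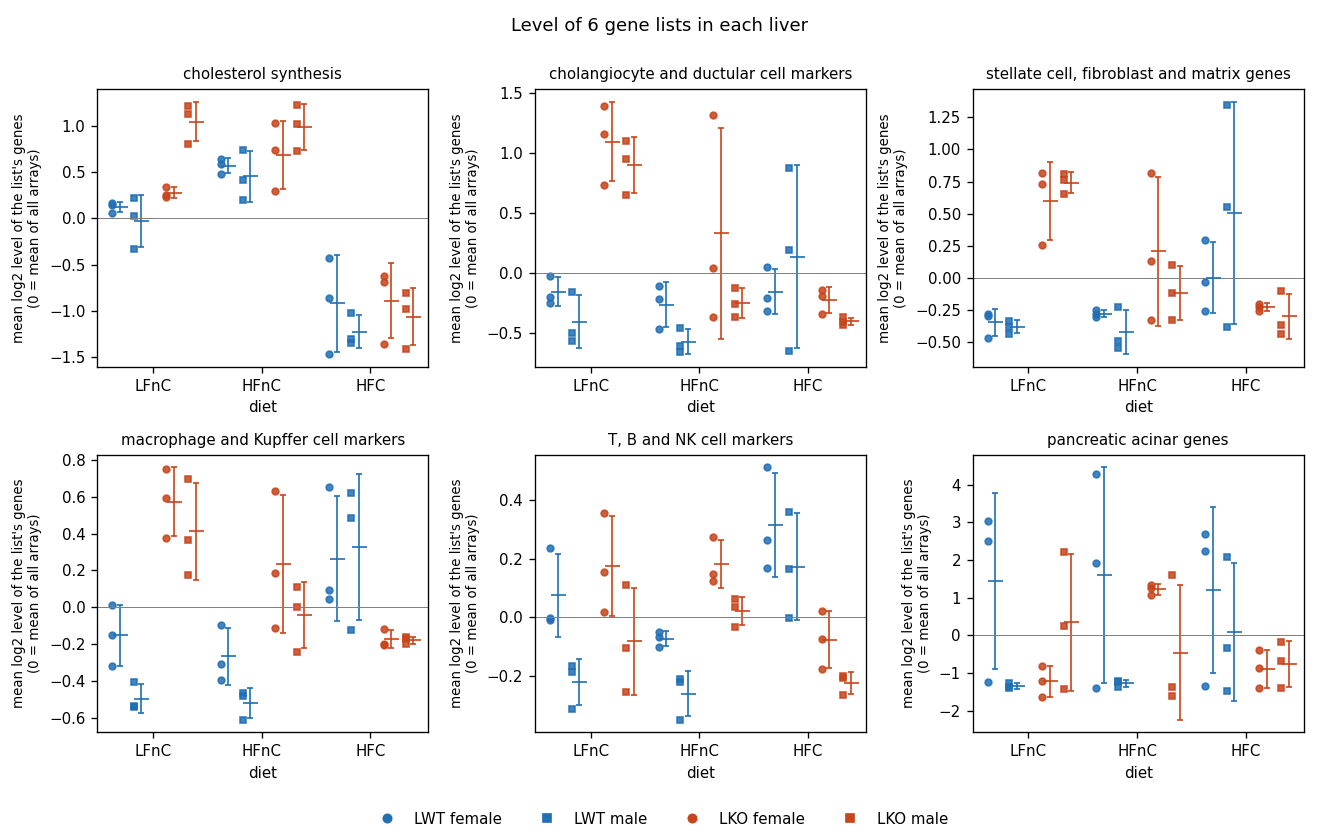
Mean log2 level of the genes of 6 lists in each liver (vertical axes, 0 is the mean of all arrays) by diet (horizontal axes), genotype (colour) and sex (marker); bars are the mean and SD of 3 mice. Ductular levels of LKO livers had a mean of 1.00 on LFnC and -0.32 on HFC; among male LWT livers on HFC, replicates 1, 2 and 3 had matrix levels of 1.35, 0.55 and -0.38; acinar levels ran from -1.64 to 4.29.

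On the high-fat diet without cholesterol, HFnC, the genotype called 4 genes, all of them also called on LFnC in the same direction. The genotype changes on HFnC and LFnC correlated at 0.7 across genes, which are not independent replicates. The direct test of a difference between these diets, the genotype by fat, called 0 genes. The counts alone thus do not show a different effect on these diets. Tinag, a basement membrane glycoprotein, rose by 2.29 (SE 0.31, adjusted p = 0.00036), the fatty acid desaturase Scd2 by 1.87 (SE 0.30, adjusted p = 0.0051) and Dpysl2 by 0.79 (SE 0.13, adjusted p = 0.0051), while Cyp51 fell by 1.64 on the log2 scale (SE 0.22, adjusted p = 0.00036). Macrophage and Kupffer cell markers had a median of 0.48 with no member called, and 10 of 16 higher adjusted over the list alone (adjusted p = 1.9e-05, or adjusted p = 0.21 with an estimated correlation). T, B and NK cell markers had a median of 0.22, with 4 of 11 higher adjusted over the list alone (adjusted p = 3.7e-05, or adjusted p = 0.21 with an estimated correlation). The medians of the matrix list (0.48, adjusted p = 0.00017), the ductular list (0.47, adjusted p = 0.00094) and cholesterol synthesis (0.35, adjusted p = 0.00017) were above 0, each with adjusted p = 0.46 with an estimated correlation. Within HFnC female LKO mice, replicate 1 had a ductular level of 1.31, and the ductular list was not called without it. Unadjusted, 2355 genes had p under 0.05 in limma. Leaving out female LKO replicate 3 gave 298 called genes, and leaving out male LWT replicate 1 or 2 gave 9 and 7.

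On HFC T, B and NK cell markers were lower in LKO than in LWT livers. Of the 152 genes called for the genotype both on LFnC and on HFC, 151 had opposite signs, where 28.7 would by chance. This may rest on male LWT replicates 1 and 2 on HFC. Without them too few genes were called on HFC to compare the signs of shared genes. The correlation of the changes across genes then went from -0.63 to -0.21 (genes are not independent replicates). That fit has 1 male LWT array on HFC. Leaving out any of several other single arrays also removed nearly all calls on HFC. The chemokines Ccl3 (-1.29, SE 0.26, adjusted p = 0.026) and Ccl5 (-1.01, SE 0.21, adjusted p = 0.027) fell, as did Cyp51 (-1.57, SE 0.22, adjusted p = 0.0014). Higher in LKO were Ranbp3l (0.73, SE 0.16, adjusted p = 0.031), Dnaja4, a heat shock cochaperone (0.37, SE 0.08, adjusted p = 0.026), and Adssl1 (0.37, SE 0.09, adjusted p = 0.046, and 0.053 with the batch as a block). Ccl3 and Ccl5 lost their calls in 11 and 12 of 15 leave-outs. T, B and NK cell markers fell, with 3 of 11 lower (9 adjusted over the list alone) and a median of -0.38 (adjusted p = 5.3e-10, or adjusted p = 0.012 with an estimated correlation) and -0.40, -0.29 and -0.48 within the batches. The leukocyte phosphatase Ptprc (-0.81), the T cell receptor chain Cd3g (-0.59) and the granzyme Gzma (-0.45) were the called members. Macrophage markers had a median of -0.49 with no member called and 11 of 16 lower adjusted over the list alone (adjusted p = 4.8e-08, or adjusted p = 0.077 with an estimated correlation). Cell division genes (median -0.50, 9 of 13 lower adjusted over the list alone, adjusted p = 2.8e-08) and the matrix list (median -0.61, 12 of 16 lower adjusted over the list alone, adjusted p = 4.8e-08) were also called, each with adjusted p = 0.33 with an estimated correlation. Pancreatic acinar genes also differed, with a median of -1.54 and no member called (adjusted p = 0.01, or adjusted p = 0.52 with an estimated correlation), as did liver endothelial markers with -0.07 (adjusted p = 0.049, or adjusted p = 0.44 with an estimated correlation). Male-biased liver genes had a median of 0.31 with 5 of 13 higher adjusted over the list alone (adjusted p = 0.00098, or adjusted p = 0.33 with an estimated correlation).

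The LWT group on HFC was uneven among males. Replicates 1 and 2 had matrix levels of 1.35 and 0.55, ductular levels of 0.87 and 0.19 and Gpnmb values of 11.25 and 10.37, against -0.38, -0.66 and 6.60 in replicate 3. With both left out, the T, B and NK cell list had a mean change of -0.49 on HFC (adjusted p = 2.8e-24), the matrix list -0.07 (adjusted p = 0.32) and the ductular list 0.09, where its median over all arrays was -0.37 (adjusted p = 0.027, or adjusted p = 0.58 with an estimated correlation). Macrophage markers (-0.24, adjusted p = 1.6e-05, where the mean over all arrays was -0.47) and cell division genes (-0.18, adjusted p = 0.027, from -0.49) were called with smaller changes, while male-biased genes (0.12, adjusted p = 0.11, from 0.48) and endothelial markers (-0.06, adjusted p = 0.2) were not. The acinar list was still called (-1.25, adjusted p = 0.018). Of the named genes only Cyp51 was then called (-1.44, adjusted p = 0.046). Ccl3 was at -0.72 (SE 0.25, adjusted p = 1), Ccl5 at -1.20 (SE 0.23, adjusted p = 0.076), Ranbp3l at 0.41, Dnaja4 at 0.40 and Adssl1 at 0.27. With the acinar level as a covariate the same 5 genes lost their calls with little change in size, such as Ccl3 at -1.32 (SE 0.28, adjusted p = 0.064). The genotype called 197 genes on HFC, 16 higher and 181 lower. With the acinar level as a covariate it called 1. The count was 93 with the batch as a block, 5 higher and 88 lower, and 78 with median centring, 22 of them higher (28.2%, against 8.12%). It ranged from 1 to 1933 when single arrays were left out, the highest without male LWT replicate 3 and 1 without male LWT replicate 1, male LKO replicate 1 or 3, female LKO replicate 2 or 3, or female LWT replicate 3.

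Over all diets, LKO livers had higher Tinag (1.54, SE 0.18, adjusted p = 1.8e-05), Mmp12 (1.38, SE 0.34, adjusted p = 0.027) and Cib3 (1.35, SE 0.20, adjusted p = 0.00074). Also higher were Scd2 (1.27, SE 0.17, adjusted p = 0.00022), the acute phase lipocalin Lcn2 (1.25, SE 0.27, adjusted p = 0.016) and Elovl7 (1.21, SE 0.27, adjusted p = 0.019). Besides Cyp51 (-1.47, SE 0.13, adjusted p = 5e-08), the acyl-CoA thioesterase Acot3 (-1.04, adjusted p = 0.033) and the leptin receptor Lepr (-0.96, adjusted p = 0.027) fell, as did Adgrf1 (-0.85, adjusted p = 0.013), Sult2a3 (-0.74, adjusted p = 0.044) and the lipase inhibitor G0s2 (-0.65, adjusted p = 0.022). Sult2a3 and Acot3 lost their calls in 31 and 15 of 39 leave-outs, Lepr without LFnC female LKO replicate 1 and Mmp12 without HFC female LWT replicate 1. With the acinar level as a covariate Sult2a3 (-0.64, adjusted p = 0.07) was not called. Cholesterol synthesis enzymes rose, 5 of 15 higher (13 adjusted over the list alone), with a median of 0.37 (adjusted p = 8.1e-12, or adjusted p = 0.25 with an estimated correlation) and 0.09, 0.39 and 0.46 by batch. Lss rose by 0.65, Mvk by 0.50, Hmgcs1 by 0.44 and Fdft1 by 0.28. Ductular markers had 6 of 9 higher (8 adjusted over the list alone; median 0.45, adjusted p = 2.1e-08, or adjusted p = 0.25 with an estimated correlation), and 0.59, 0.35 and 0.40 within batches. The matrix list had no called member and 11 of 16 higher adjusted over the list alone (median 0.30, adjusted p = 3.9e-07, or adjusted p = 0.27 with an estimated correlation). PPARalpha targets had 2 of 14 lower (7 adjusted over the list alone; median -0.17, adjusted p = 2.3e-05, or adjusted p = 0.27 with an estimated correlation). Macrophage markers had 5 higher and 1 lower of 16 (8 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.00019, or adjusted p = 0.27 with an estimated correlation). All these changes average over the diets and need not hold on each. On HFC the mean macrophage level was lower in LKO than in LWT, -0.171 against 0.265 in females and -0.176 against 0.328 in males. The mean matrix level on HFC was -0.226 in LKO against 0.005 in LWT females, and -0.297 against 0.505 in males. In total 520 genes were called, 405 higher and 115 lower, or 573 with median centring, 347 of them higher (60.6%, against 77.9%). The count ran from 262 to 1345 as single arrays were left out, highest without HFC male LWT replicate 1 and 1189 without HFnC female LKO replicate 3. Without both HFC male LWT replicates 1 and 2 it was 1971.

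In males, where 9 LKO mice were set against 9 LWT mice, the enzymes of cholesterol synthesis stood out. Of 15 members 6 rose and none fell (15 higher adjusted over the list alone), with a median of 0.61 (adjusted p = 1.4e-25, or adjusted p = 0.028 with an estimated correlation) and 0.62, 0.20 and 0.88 by batch. Lss rose by 0.98, Mvd by 0.82, Mvk by 0.70 and Hsd17b7 by 0.56. Of 9 lists called, 8 were higher, and this was the only one called with an estimated correlation. The others had smaller medians: 0.28 for fatty acid and triglyceride synthesis (adjusted p = 0.00018, or adjusted p = 0.42 with an estimated correlation), 0.26 for macrophage markers (0.00016, or 0.26), 0.25 for ductular markers (0.00022, or 0.41), 0.22 for the matrix list (0.0022, or 0.59), 0.21 for sterol-responsive genes (9.6e-05, or 0.069), 0.12 for the acute phase (0.00046, or 0.41), 0.10 for neutrophil markers (0.0017, or 0.26) and -0.14 for PPARalpha targets (0.0015, or 0.44). Scd2 (1.52, SE 0.24, adjusted p = 0.0092), Tinag (1.47, SE 0.25, adjusted p = 0.01) and Orm3, an orosomucoid (1.28, SE 0.27, adjusted p = 0.035), rose. Cyp51 (-1.5, SE 0.18, adjusted p = 7.1e-05), Dpy19l3 (-0.66, adjusted p = 0.023) and Cecr2 (-0.36, adjusted p = 0.046, and 0.05 with the batch as a block) fell. Orm3, Dpy19l3 and Cecr2 lost their calls in 13, 8 and 17 of 21 leave-outs, and Cecr2 (-0.36, adjusted p = 0.063) also with the acinar level as a covariate. Of all genes 36 were called, 29 higher and 7 lower, and the count ran from 15 to 94 without single arrays (15 without LFnC male LKO replicate 1 or HFC male LKO replicate 3, 94 without HFC male LWT replicate 1). Without HFC male LWT replicates 1 and 2 it was 437.

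In females the genotype called 406 genes, 260 higher and 146 lower, and 17 with only the female groups fitted. That fit has fewer samples and its own estimate of the spread, so the 406 calls rest on the spread shared with the male groups. The same step took the count in males only from 36 to 25. The reason for the larger fall in females was not tested. Cib3 rose by 1.89 (SE 0.29, adjusted p = 0.0021), Elovl7 by 1.86 (SE 0.38, adjusted p = 0.016) and Sprr1a, a cornified envelope protein, by 1.64 (SE 0.40, adjusted p = 0.03). The female-biased Sult3a2 (-2.15, SE 0.47, adjusted p = 0.019) and A1bg (-1.86, SE 0.48, adjusted p = 0.039) fell with Cyp51 (-1.45, SE 0.18, adjusted p = 0.00013). Female-biased liver genes had 2 of 10 lower (6 adjusted over the list alone; median -0.78, adjusted p = 0.00012, or adjusted p = 0.26 with an estimated correlation), with -1.38, -0.23 and -0.56 by batch. The called members were A1bg and the transcription factor Cux2 (-0.76). NRF2 targets had 2 of 8 higher (4 adjusted over the list alone; median 0.29, adjusted p = 9.9e-06, or adjusted p = 0.26 with an estimated correlation), Gclm and Gclc, both subunits of an enzyme of glutathione synthesis. Ductular markers had 5 of 9 higher (7 adjusted over the list alone; median 0.67, adjusted p = 1.2e-06, or adjusted p = 0.26 with an estimated correlation), with 1.19, 0.47 and 0.28 by batch. Macrophage markers had a median of 0.23 (adjusted p = 0.036, or 0.051 with the batch as a block, or adjusted p = 0.52 with an estimated correlation). Pancreatic acinar genes differed between these groups as well, with a median of -1.75 (adjusted p = 0.00043, or adjusted p = 0.5 with an estimated correlation). The count of 406 was 1487 without HFnC female LKO replicate 3, 76 without HFC female LWT replicate 1 and 61 with the acinar level as a covariate, where Elovl7 (1.82, adjusted p = 0.055), Sprr1a (1.52, adjusted p = 0.094) and A1bg (-2.10, adjusted p = 0.063) were not called. A1bg and Sprr1a lost their calls in 14 and 12 of 21 leave-outs, and Sult3a2 without HFnC female LKO replicate 1.

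The difference between the sexes in the effect of the genotype was tested as females minus males. Fatty acid and triglyceride synthesis genes had a median difference of -0.69 (no member called, 9 of 14 lower adjusted over the list alone, adjusted p = 1.2e-10) and cholesterol synthesis genes -0.43 (8 of 15 lower adjusted over the list alone, adjusted p = 1.2e-10), each with adjusted p = 0.19 with an estimated correlation. By batch the cholesterol synthesis difference was -0.92, 0.21 and -0.70. Single genes that differed were Dpy19l3 (0.98), Gss, a glutathione synthase (0.92), the tight junction protein Ocln (0.59) and B4galnt1 (0.39). A negative difference was called for Tfpi2 (-0.78), Ces2e (-0.70), Dhrs7b (-0.59), Mipep (-0.53), Isoc2b (-0.52, adjusted p = 0.043, or 0.084 with the batch as a block) and Ccdc159 (-0.51). Their adjusted p ran from 0.021 to 0.043. Acinar genes differed too, with a median of -2.32 (adjusted p = 3.9e-05, or adjusted p = 0.29 with an estimated correlation). The count of called genes was 14, 5 higher and 9 lower, and 10 with median centring, 5 of them higher. It was 1 without LFnC male LKO replicate 1, 42 without HFnC female LKO replicate 3 and 3 to 27 without any other single array. With the acinar level as a covariate it was 1. All 10 named genes then lost their calls, although their differences changed little: Dpy19l3 was at 0.86 (SE 0.20, against 0.19 before), Ocln at 0.58 (SE 0.13, against 0.12) and Tfpi2 at -0.77 (SE 0.16, against 0.14). The calls ended because the unadjusted p rose, for Tfpi2 from 5.8e-06 to 3.7e-05, which the adjustment over all genes no longer passed. Without HFC male LWT replicates 1 and 2 only Dpy19l3 (1.12), Tfpi2 (-0.87) and Dhrs7b (-0.64) of the 10 were called. Females and males shared 6 called genes, all in the same direction.

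Dietary cholesterol lowered the sterol pathway in LWT livers. Sqle, squalene epoxidase (-3.23, SE 0.33, adjusted p = 6.7e-07), Cyp51 (-2.53, SE 0.22, adjusted p = 3.6e-08) and the sterol oxidase Msmo1 (-2.33, SE 0.27, adjusted p = 3.9e-06) fell. Falls were also called for Lss (-2.06, SE 0.24, adjusted p = 3.9e-06), Chrna4 (-2.05, SE 0.40, adjusted p = 0.0027) and Rdh11 (-2.02, SE 0.23, adjusted p = 3.7e-06). All 15 measured cholesterol synthesis genes were lower (15 adjusted over the list alone; median -1.55, adjusted p = 3.6e-43, or adjusted p = 0.00093 with an estimated correlation), with -1.46, -1.84 and -1.46 within the batches. Sterol-responsive genes outside the pathway had 6 of 8 lower (6 adjusted over the list alone; median -0.78, adjusted p = 2.6e-11, or adjusted p = 0.00093 with an estimated correlation), among them the cholesterol carrier Stard4 (-1.17), Mmab (-0.96) and the regulator Srebf2 (-0.60). LXR targets, which oxysterols switch on, had 3 of 10 higher and none lower (5 and 1 adjusted over the list alone; median 0.32, adjusted p = 3.6e-05, or adjusted p = 0.018 with an estimated correlation): Lpl, Abcg1 (0.85) and Abca1 (0.34). Fatty acid and triglyceride synthesis had 3 of 14 lower (7 adjusted over the list alone; median -0.52, adjusted p = 1.7e-05, or adjusted p = 0.21 with an estimated correlation), with Acly at -1.21 and Acacb at -1.17. Lipid droplet genes had 4 of 12 higher (5 adjusted over the list alone; median 0.44, adjusted p = 4.5e-05, or adjusted p = 0.061 with an estimated correlation), namely Cidec (1.23), Plin4 (0.96), Pparg (0.87) and Cd36 (0.82).

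Markers of immune cells also rose with cholesterol in LWT livers. Macrophage markers had 10 of 16 higher and none lower (12 adjusted over the list alone; median 0.66, adjusted p = 2.6e-11, or adjusted p = 0.009 with an estimated correlation), with 0.90, 0.47 and 0.60 by batch. Lyz2 rose by 1.00, Ctss by 0.97, Adgre1 by 0.69 and Cd5l by 0.64. T, B and NK cell markers had 6 of 11 higher (7 adjusted over the list alone; median 0.40, adjusted p = 1.2e-08, or adjusted p = 0.009 with an estimated correlation), with Ptprc at 0.97, Cd3g at 0.61 and Cd8a at 0.43. Gpnmb (2.56, SE 0.69, adjusted p = 0.027), Mmp12 (2.48, SE 0.59, adjusted p = 0.012) and the serum amyloid Saa1 (1.76, SE 0.45, adjusted p = 0.021) rose, and so did Ccl3 (1.74, SE 0.26, adjusted p = 0.00018), Lcn2 (1.74, SE 0.47, adjusted p = 0.029) and Lpl (1.73, SE 0.25, adjusted p = 0.00014). The matrix list had 6 of 16 higher (12 adjusted over the list alone; median 0.70, adjusted p = 3.7e-08, or adjusted p = 0.16 with an estimated correlation). The ductular list had 1 of 9 higher, Krt23 (1.38), with a median of 0.31 (adjusted p = 0.01, or adjusted p = 0.35 with an estimated correlation). Without male LWT replicates 1 and 2 on HFC, Ccl3 (1.17, adjusted p = 0.037) and Lpl (1.24, adjusted p = 0.021) were still called. Gpnmb (1.15, adjusted p = 0.81), Mmp12 (1.28, adjusted p = 0.62), Saa1 (1.40, adjusted p = 0.43) and Lcn2 (1.25, adjusted p = 0.57) were then not called. Mean changes in the matrix, ductular and lipid droplet lists were then 0.16 (adjusted p = 0.086), 0.01 (adjusted p = 0.63) and 0.24 (adjusted p = 0.074, from 0.50). Macrophage markers (0.46) and T, B and NK cell markers (0.50) were still called. Cholesterol called 918 genes in LWT, 689 higher and 229 lower, or 1157 with median centring, 520 of them higher (44.9%, against 75.1%). The count was 51 without both of those arrays, 2197 without HFC male LWT replicate 3, 398 without replicate 1, 478 without HFC female LWT replicate 3 and 506 without HFnC female LWT replicate 3.

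In LKO livers cholesterol lowered the same pathway. Sqle (-4.05, SE 0.33, adjusted p = 4.9e-09), Chrna4 (-2.58, SE 0.40, adjusted p = 0.00029) and Lss (-2.48, SE 0.24, adjusted p = 5.7e-08) fell. So did Cyp51 (-2.46, SE 0.22, adjusted p = 1.9e-08), Msmo1 (-2.46, SE 0.27, adjusted p = 7.4e-07) and Tinag (-2.35, SE 0.31, adjusted p = 1.9e-05). Of 15 cholesterol synthesis genes 14 were lower (14 adjusted over the list alone; median -1.80, adjusted p = 2.4e-53, or adjusted p = 0.00039 with an estimated correlation), with -1.93, -1.62 and -1.77 by batch, and Hmgcs1 was at -2.31. Sterol-responsive genes had 4 of 8 lower (5 adjusted over the list alone; median -0.86, adjusted p = 9.1e-12, or adjusted p = 0.00065 with an estimated correlation), with Rdh11 at -2.24 and Srebf2 at -0.93. Adam11 (1.98, SE 0.16, adjusted p = 4.9e-09), Sult2a3 (1.72, adjusted p = 0.0089) and the elongase Elovl3 (1.55, adjusted p = 0.046, or 0.054 with the batch as a block) rose, as did the carbonic anhydrase Car14 (1.16, adjusted p = 4.6e-05), the NADPH oxidase Nox4 (1.06, adjusted p = 0.033) and Flvcr2 (0.95, adjusted p = 0.0029). Elovl3 and Nox4 lost their calls in 13 and 11 of 15 leave-outs, and Nox4 (1.00, adjusted p = 0.071) also with the acinar level as a covariate. LXR targets had Abca1 higher (0.39) and Pltp lower (-1.23) of 10 (median 0.23, adjusted p = 0.0022, or adjusted p = 0.094 with an estimated correlation). Macrophage markers had a median of -0.33 with no member called (adjusted p = 0.048, or 0.067 with the batch as a block, or adjusted p = 0.48 with an estimated correlation). The matrix list had -0.37 (adjusted p = 0.0043, or adjusted p = 0.49 with an estimated correlation) and T, B and NK markers -0.26 (adjusted p = 0.00012, or adjusted p = 0.094 with an estimated correlation). In all 198 genes were called, 66 higher and 132 lower, or 200 with median centring, 105 of them higher (52.5%, against 33.3%). The count was 668 without HFnC female LKO replicate 3, 98 without HFnC male LKO replicate 3, 112 without HFC male LKO replicate 1 and 126 without HFC female LKO replicate 1. LWT and LKO shared 63 genes called for cholesterol, 10 of them higher in both, 48 lower in both and 5 in opposite directions, where chance would give 2.31, 1.54 and 5.39. The changes of all genes correlated at -0.17 across genes, which are not independent replicates. Without HFC male LWT replicates 1 and 2 the genotypes shared 32 genes, 2 higher in both, 26 lower in both and 4 in opposite directions, and the correlation was 0.17.

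The test of whether cholesterol acted differently in LKO and LWT livers called 1136 genes, 236 higher and 900 lower. T, B and NK cell markers had 6 of 11 lower (9 adjusted over the list alone; median -0.66, adjusted p = 2.8e-09, or adjusted p = 0.018 with an estimated correlation), with -0.77, -0.46 and -0.52 within the batches. Macrophage markers had 11 of 16 lower (12 adjusted over the list alone; median -1.0, adjusted p = 2.3e-08, or adjusted p = 0.057 with an estimated correlation), and the matrix list 10 of 16 (12 adjusted over the list alone; median -1.08, adjusted p = 1e-07, or adjusted p = 0.3 with an estimated correlation). Cell division had 4 of 13 lower (10 adjusted over the list alone; median -0.70, adjusted p = 8.6e-07, or adjusted p = 0.3 with an estimated correlation). The named genes were Gpnmb (-4.00, SE 0.97, adjusted p = 0.014), Mmp12 (-3.35, SE 0.83, adjusted p = 0.016) and Ly6d (-2.97, SE 0.79, adjusted p = 0.024). A positive difference was called for the male-biased steroid enzyme Hsd3b5 (3.16, SE 0.92, adjusted p = 0.039), Adgrf1 (1.77, adjusted p = 0.015) and Mup21 (1.77, adjusted p = 0.042). With the acinar level as a covariate 726 genes were called. Hsd3b5 (3.04, adjusted p = 0.075) and Mup21 (1.67, adjusted p = 0.085) were then not called, while the other named genes were. The difference in Cyp51 was 0.07 (SE 0.31, adjusted p = 0.94). Without the male LWT replicates 1 and 2 on HFC 106 genes were called, 2 of them higher, and none of these 6 named genes was among them: Gpnmb (-2.60, adjusted p = 0.26), Mmp12 (-2.15, adjusted p = 0.29), Ly6d (-1.68, adjusted p = 0.4), Hsd3b5 (1.43, adjusted p = 0.51), Adgrf1 (1.18, adjusted p = 0.25) and Mup21 (1.52, adjusted p = 0.31). The T, B and NK (-0.75), macrophage (-0.73), matrix (-0.47) and cell division (-0.43) lists were still called by their mean change. Median centring moved the median of all genes by 0.111 in this comparison and called 2285 genes, 1551 of them higher (67.9%, against 20.8%). Quantile normalisation called 1202, 420 higher (34.9%), so the share that was lower depends on the scaling. Single arrays moved the count to 2746 (without HFC male LWT replicate 3), 2130 (HFnC female LKO replicate 3), 592 (HFC male LWT replicate 1), 654 (HFnC female LKO replicate 1) and 689 (HFC female LWT replicate 3).

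The high-fat diet without cholesterol lowered CAR and PXR targets in LWT livers relative to chow. Cyp2b10, a drug-metabolising cytochrome and CAR target, fell by 2.44 on the log2 scale (SE 0.43, adjusted p = 0.008), and Cyp3a11, a PXR target, fell by 0.68. They are 2 of 7 members of their list (5 lower adjusted over the list alone; median -0.68, adjusted p = 4.7e-07, or adjusted p = 0.0023 with an estimated correlation), which had -0.53, -0.77 and -0.44 by batch. Gria3 (1.44, SE 0.24, adjusted p = 0.0047), Serpina12 (1.39, SE 0.27, adjusted p = 0.018) and the fatty acid binding protein Fabp2 (1.07, SE 0.14, adjusted p = 5e-04) rose. So did Pgm3 (1.07, SE 0.17, adjusted p = 0.0019), Rassf6 (0.79) and Sel1l3 (0.79). Mmd2 (-1.59, SE 0.27, adjusted p = 0.0054), the mitochondrial sulfur dioxygenase Ethe1 (-1.03, SE 0.15, adjusted p = 0.0014), Flvcr2 (-0.81, adjusted p = 0.042, or 0.051 with the batch as a block), the exporter Abcc3 (-0.75, adjusted p = 0.024) and Ndrg1 (-0.70, adjusted p = 0.042) fell. Flvcr2, Ndrg1, Abcc3 and Serpina12 lost their calls in 11, 11, 9 and 6 of 15 leave-outs, and Cyp2b10 without LFnC male LWT replicate 3. Cholesterol synthesis (median 0.43, 9 of 15 higher adjusted over the list alone, adjusted p = 7.2e-11) and fatty acid and triglyceride synthesis (median 0.67, 8 of 14 higher adjusted over the list alone, adjusted p = 1.6e-10) had no called member, each with adjusted p = 0.13 with an estimated correlation. Of all genes 37 were called, 19 higher and 18 lower (36 with median centring, 24 higher, 66.7% against 51.4%). The count was 61 without LFnC male LWT replicate 1, 58 without LFnC female LWT replicate 3, 13 without LFnC male LWT replicate 3 and 21 without HFnC female LWT replicate 1.

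In LKO livers the same change of diet lowered ductular markers. Of 9 members 8 fell (8 adjusted over the list alone; median -0.97, adjusted p = 3.4e-09, or adjusted p = 0.1 with an estimated correlation), with -0.60, -1.12 and -1.19 within batches. Cftr (-1.5), Epcam (-1.40) and Sox9 (-0.99) were among them. The matrix list had 5 of 16 lower (11 adjusted over the list alone; median -0.66, adjusted p = 2.3e-08, or adjusted p = 0.27 with an estimated correlation), and neutrophil markers 6 of 10 (6 adjusted over the list alone; median -0.37, adjusted p = 0.00012, or adjusted p = 0.1 with an estimated correlation), with S100a8 at -0.77. The estrogen sulfotransferase Sult1e1 (-2.29, SE 0.45, adjusted p = 0.0048), matrilysin Mmp7 (-2.02, SE 0.34, adjusted p = 0.0016) and Cyp2c55 (-1.95, SE 0.35, adjusted p = 0.0024) fell, as did Tspan8 (-1.88, adjusted p = 0.0096), Wfdc18 (-1.72, adjusted p = 0.0096) and Orm2 (-1.70, adjusted p = 0.003). Slco1a1, an organic anion transporter (1.88, SE 0.43, adjusted p = 0.015), the deiodinase Dio1 (1.35, adjusted p = 0.01) and Fabp2 (1.13, SE 0.14, adjusted p = 0.00014) rose. Smaller rises were called for Angptl4 (1.08, adjusted p = 0.0029), Lpin1 (1.06, adjusted p = 0.019) and Vnn1 (1.02, adjusted p = 0.041). The count was 991, 354 higher and 637 lower, or 1313 with median centring, 757 of them higher (57.7%, against 35.7%). It was 2650 without HFnC female LKO replicate 1, 167 without replicate 3 of that group, 223 without LFnC male LKO replicate 2 and 306 to 623 without 6 other single arrays. Slco1a1, Dio1, Tspan8 and Wfdc18 lost their calls without HFnC female LKO replicate 3, and Vnn1 and Lpin1 in 13 and 8 of 15 leave-outs. LWT and LKO shared 10 genes called for this diet, all in the same direction. The test of the difference between the genotypes called 0 genes in limma (4270 at an unadjusted p under 0.05), and 806 without HFnC female LKO replicate 1. Its list medians were -0.77 for ductular markers (5 of 9 lower adjusted over the list alone, adjusted p = 1.1e-05) and -0.61 for the matrix list (adjusted p = 1.3e-06), each with adjusted p = 0.76 with an estimated correlation.

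Sex differences were large in both genotypes. In LWT livers, with 9 females against 9 males, the cytochrome Cyp2b13 was 5.93 higher in females (SE 0.29, adjusted p = 6.3e-15) and Cyp3a16 5.53 higher (SE 0.63, adjusted p = 6.8e-07). The sulfotransferases Sult2a3 and Sult3a1 were 5.50 (SE 0.28, adjusted p = 2.9e-14) and 4.81 (SE 0.73, adjusted p = 6.7e-05) higher, Slc22a26 4.38 and the hydroxyacid oxidase Hao2 4.35. In LWT males on LFnC Sult3a1 read near the bottom of the array's range, so the size of its difference is not exact. Cyp4a12a (-6.06, SE 0.20, adjusted p = 2.5e-19), Cyp4a12b (-6.02, SE 0.15, adjusted p = 1.5e-22), Slco1a1 (-5.01), Hsd3b5 (-4.00), Nat8f5 (-3.41) and Elovl3 (-3.11) were lower in females. All 10 female-biased liver genes rose (10 adjusted over the list alone; median 2.99, adjusted p = 2.2e-26, or adjusted p = 4.4e-05 with an estimated correlation), and 11 of 13 male-biased genes fell (13 adjusted over the list alone; median -1.99, adjusted p = 1.1e-39, or adjusted p = 6.6e-06 with an estimated correlation). Liver endothelial markers had 7 of 10 higher in females (8 adjusted over the list alone; median 0.21, adjusted p = 1.3e-06, or adjusted p = 0.027 with an estimated correlation). Fatty acid and triglyceride synthesis had 4 of 14 higher (11 adjusted over the list alone; median 0.44, adjusted p = 4.2e-08, or adjusted p = 0.22 with an estimated correlation), with Pnpla3 at 1.33 and Acaca at 0.84. Pancreatic acinar genes had 4 of 6 higher (6 adjusted over the list alone; median 2.36, adjusted p = 2.1e-05, or adjusted p = 0.26 with an estimated correlation): Clps (2.61), Cela2a (2.10), Prss2 (1.72) and Cela1 (1.49). The count was 1259, 597 higher and 662 lower, and 524 with the acinar level as a covariate.

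In LKO livers Cyp2b13 (5.50, SE 0.29, adjusted p = 3.4e-14), Slc22a26 (4.22), Sult2a3 (4.19), Cyp2b9 (4.17), Cyp2a22 (3.57) and Cyp3a16 (3.41, SE 0.63, adjusted p = 0.00097) were higher in females. Cyp4a12b (-6.02, SE 0.15, adjusted p = 1.5e-22), Cyp4a12a (-5.86), Slco1a1 (-4.50), Nat8f5 (-4.18), Elovl3 (-3.95) and Hsd3b5 (-3.58) were lower. Female-biased genes had 7 of 10 higher (10 adjusted over the list alone; median 1.56, adjusted p = 1.6e-18, or adjusted p = 0.00053 with an estimated correlation) and male-biased genes 12 of 13 lower (12 adjusted over the list alone; median -1.92, adjusted p = 8.5e-42, or adjusted p = 4.3e-06 with an estimated correlation). Bile acid synthesis had 6 of 12 lower in females (8 adjusted over the list alone; median -0.20, adjusted p = 1.1e-07, or adjusted p = 0.031 with an estimated correlation), among them Cyp7b1 (-2.15), the sterol 12-alpha-hydroxylase Cyp8b1 (-1.43), Scp2 (-0.70) and Hsd3b7 (-0.39). Cholesterol synthesis had 2 of 15 lower, Mvk and Mvd (5 adjusted over the list alone; median -0.31, adjusted p = 7e-05, or adjusted p = 0.55 with an estimated correlation). The heme synthesis gene Alas2 was lower (-1.64). The count was 1085, 498 higher and 587 lower. The genotypes shared 440 genes called for sex, 436 in the same direction, and the changes of all genes correlated at 0.72 across genes, which are not independent replicates.

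Fat and cholesterol were also tested for a difference between females and males, averaged over the genotypes. For fat 0 genes were called in limma (880 at an unadjusted p under 0.05), and fatty acid and triglyceride synthesis had the smallest list p, a median difference of 0.34 (adjusted p = 9.5e-05, or adjusted p = 0.39 with an estimated correlation). For cholesterol the one gene called was Gnai1, an inhibitory G protein subunit, with -1.04 (SE 0.15, adjusted p = 0.0023), and the matrix list had a median of -0.44 (adjusted p = 1.7e-06, or adjusted p = 0.34 with an estimated correlation). That list had -1.62, -0.25 and 0.48 within batches 1, 2 and 3, and its mean change was 0 (adjusted p = 0.97) without HFC male LWT replicates 1 and 2, so the difference rests on those arrays.

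**Figure D3:**
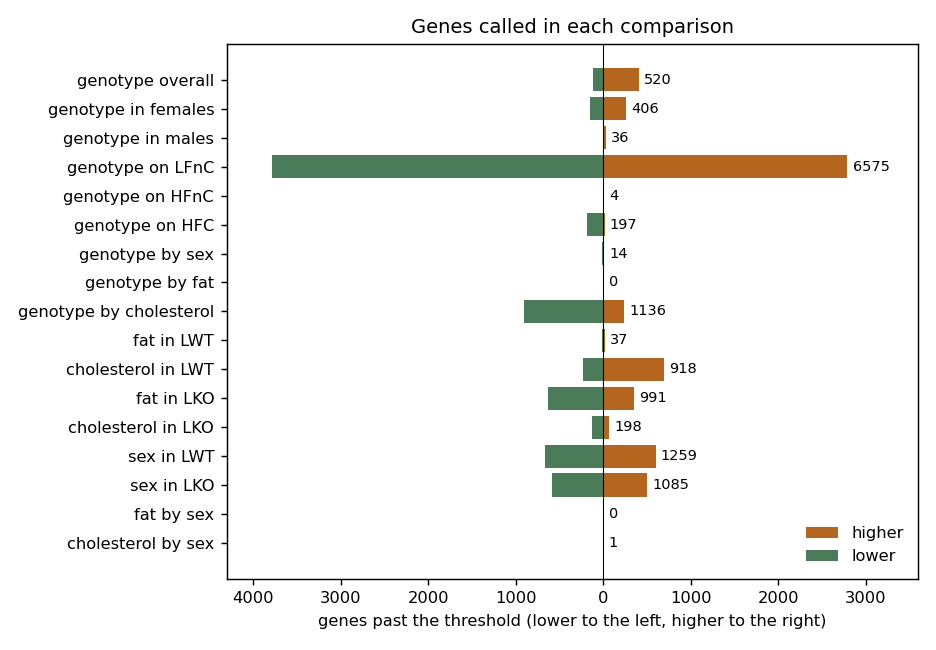
Number of genes called in each comparison (horizontal axis; lower to the left, higher to the right; total at the end of each bar). The genotype on LFnC called 6575 genes, against 4 on HFnC and 197 on HFC. The test of a difference between LFnC and HFnC, the genotype by fat, called 0 genes.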

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

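The tests of the 3 patterns weighed in this part were chosen only after the results were seen; the tests of differences between groups and the regroupings of the arrays were planned.

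The effect of the genotype differed between females and males in 14 genes. The differences (females minus males) were 0.98 for Dpy19l3, 0.92 for Gss, 0.59 for Ocln, 0.39 for B4galnt1, -0.78 for Tfpi2, -0.70 for Ces2e, -0.59 for Dhrs7b, -0.53 for Mipep, -0.52 for Isoc2b and -0.51 for Ccdc159. With the acinar level as a covariate the count was 1, and none of these named genes was called. The effect of cholesterol differed between LKO and LWT livers in 1136 genes, with 3.16 for Hsd3b5, 1.77 for Adgrf1, 1.77 for Mup21, -4.00 for Gpnmb, -3.35 for Mmp12 and -2.97 for Ly6d. Without HFC male LWT replicates 1 and 2 the count was 106 and none of these 6 genes was called. Its effect differed between the sexes in 1 gene, Gnai1 (-1.04). Among 4919 rows of the array with several gene symbols or none, which the comparisons left out, the genotype on LFnC called 971, 215 higher and 756 lower. No formal test for single outlying arrays within the groups of 3 mice was run. Leaving out single arrays showed that many counts depend on them. The count for the genotype on HFC went from 197 to 1 without male LWT replicate 1 and to 1933 without male LWT replicate 3.

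For each comparison the arrays were regrouped at random at the same sizes within the levels of the other factors, 100 groupings in all with the real one (for differences of differences, after removing the effects of the other terms), and the groupings that called at least as many genes were counted, the real one included. For the genotype on LFnC no other grouping called as many genes as the real one (6575 against at most 3791). The same held for the genotype on HFC (197 against 14) and the genotype by cholesterol (1136 against 1). The count on HFC was 0 with only that comparison's groups fitted and 1 with the acinar level as a covariate. It can also be excluded for fat in LWT (1; 37 against 4), cholesterol in LWT (1; 918 against 482), cholesterol in LKO (1; 198 against 49), sex in LWT (1; 1259 against 52) and sex in LKO (1; 1085 against 98). Few groupings reached the real count for the genotype over all mice (3 groupings, 520 against 5549), in females (4 groupings, 406 against 1789) and on HFnC (2 groupings, 4 against 10). The same held for the genotype by sex (2 groupings, 14 against 63, and 1 gene with the acinar level as a covariate) and fat in LKO (3 groupings, 991 against 1835). Another grouping called more genes than the real one in each, so chance is argued against only weakly there. Chance is not argued against for the genotype in males (7 groupings, 36 against 6391) or cholesterol by sex (7 groupings, 1 against 64). A grouping that calls several times the real count, as in these comparisons other than fat in LKO, points to a structure of the samples, whose source was not tested. For the genotype by fat (100; 0 against 106) and fat by sex (100; 0 against 2) no gene was called.

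The first pattern is the pair of male LWT arrays on HFC, replicates 1 and 2, with high matrix (1.35 and 0.55) and ductular (0.87 and 0.19) levels where replicate 3 had -0.38 and -0.66. A wrong genotype label is argued against by Cyp51, which read 8.24 or more in the pair and at most 7.12 in LKO mice on HFC, and another diet by their cholesterol synthesis levels of -1.02 or less, below the lowest level of -0.33 on LFnC or HFnC. Pancreatic tissue is argued against in replicate 2 by an acinar level of -1.49 (median of all arrays -0.84), and in replicate 1 by the other 5 LWT arrays with a higher acinar level, whose matrix levels reached 0.30. What stays open, as untested, is a difference between mice of one group, for example in how far the liver had responded to the diet.

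The second pattern is the acinar level, which ran from -1.64 to 4.29 and differed between arrays of one group. Pancreatic tissue in part of the liver samples may account for it. The 6 acinar genes moved together, with a lowest correlation of 0.88 between any pair of them in deviations from the group means. Joint expression of these genes in the liver could give the same, so the correlation cannot tell the 2 apart. Sex as the whole cause is argued against by 4 of 9 female LWT arrays that lie below the highest male LWT array (2.09). The list was called for the genotype in females, on HFC and by sex, for cholesterol in LKO, for sex in LWT and for fat and cholesterol by sex. Whether its genes reflect expression in the liver there thus stays open. No biological explanation within the design was tested beyond sex.

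The third pattern is the set of genes called by the genotype on LFnC. A lower share of hepatocytes that raises every other cell type alike is argued against by the endothelial minus ductular change of -1.32 (SE 0.119), with ductular markers at 1.28 (SE 0.13) and endothelial markers at -0.04 (SE 0.0532). The scaling of the arrays as the whole cause is argued against only weakly. Under quantile normalisation 4973 of the 6575 called genes kept their call and sign. That setting moved the median change of all genes only from -0.069 to -0.042, so it tested the scaling little. Under median centring 6013 kept call and sign. It moved that median further down, to -0.13, so it was no test for the lower genes. A response of liver tissue to the loss of Cyp51, with more ductular, matrix and macrophage cells or more expression per cell, remains a hypothesis drawn from these same data. No test here told cell number from expression per cell.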

How the results depend on the processing

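The alternatives that left out HFC male LWT replicates 1 and 2 or used the acinar level as a covariate were chosen after seeing the data; all others were planned. With the batch as a block 125 of 130 gene calls and 171 of 173 list calls stood, and the genotype on HFC called 93 genes. Averaging probe sets kept all 130 gene and 173 list calls, with 53 genes for fat in LWT. Trend and robust moderation kept 123 gene calls and all 173 list calls. Removing dim genes kept the 115 gene calls still tested and 134 list calls, with 4315 genes called for the genotype on LFnC and 57 for fat in LWT. Quantile normalisation kept 126 gene and 163 list calls, with 110 genes for the genotype on HFC and 1 for the genotype by fat; median centring kept 127 and 164, with 9982 on LFnC, 78 on HFC, 4 by fat and 2285 by cholesterol. An estimated correlation kept 18 list calls.

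Array weights ran from 0.267 to 7.83, kept 129 gene and 143 list calls and raised every count: genotype over all mice 4096, in females 1940, in males 3683, on LFnC 10579, on HFnC 4299, on HFC 3657, by sex 900, by fat 5289, by cholesterol 5603, fat in LWT 2936, cholesterol in LWT 5277, fat in LKO 7356, cholesterol in LKO 4051, sex in LWT 3427, sex in LKO 4261, fat by sex 1000 and cholesterol by sex 524. They turned the mean change of cholesterol synthesis in the genotype by fat to 0.09. In some groups 1 mouse dominated. HFnC female LKO replicate 2 had a weight of 7.83, against 0.267 and 0.678 in replicates 1 and 3. HFC male LWT replicate 2 had 6.25, against 0.35 and 0.296 in replicates 1 and 3. The higher counts thus need not mean more changed genes. Fitting only a comparison's groups, which leaves fewer samples to estimate the spread, kept 69 of 108 gene and 150 of 156 list calls and gave 17 genes for the genotype in females, 0 on HFnC, 0 on HFC, 713 by cholesterol, 313 for cholesterol in LWT, 72 for fat in LKO and 111 for cholesterol in LKO.

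Without HFC male LWT replicates 1 and 2, 43 of 65 gene calls and 56 of 84 list calls stood. The counts were 1971 for the genotype over all mice, 437 in males, 5 on HFC, 6 by sex, 106 by cholesterol, 51 for cholesterol in LWT and 3 for cholesterol by sex. The mean ductular change turned from -0.30 to 0.09 for the genotype on HFC. For cholesterol in LWT it fell from 0.41 to 0.01, which kept its sign but turned relative to the other genes. The lone male LWT array on HFC is then assumed to vary like the other groups. With the acinar covariate 107 gene and 156 list calls stood, and the counts were 61 in females, 1 on HFC, 1 by sex, 726 by cholesterol, 524 for sex in LWT and 1 for fat by sex; the acinar mean change in cholesterol by sex went to 0, as the covariate is the mean of that list.

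Leaving out single arrays or whole batches gave 16 to 1345 genes for the genotype over all mice, 1 to 1487 in females, 1 to 177 in males, 2037 to 7210 on LFnC, 0 to 298 on HFnC, 0 to 1933 on HFC, 0 to 42 by sex, 0 to 806 by fat and 89 to 2746 by cholesterol. For fat in LWT the range was 2 to 61, for cholesterol in LWT 249 to 2197, for fat in LKO 1 to 2650, for cholesterol in LKO 54 to 668, for sex in LWT 327 to 1382, for sex in LKO 344 to 1312, for fat by sex 0 to 2 and for cholesterol by sex 0 to 4. Without 1 of the batches the mean change ran from -0.27 to 0.02 for fatty acid and triglyceride synthesis on HFnC and from -0.34 to 0 for bile acid synthesis in the genotype by sex. In cholesterol by sex it ran from -0.47 to 0.17 for NRF2 targets and from -0.89 to 0.12 for the matrix list. Each was highest without batch 1, where the test's direction turned. The cause of these changes was not tested; leaving out arrays also leaves fewer samples. Signal over background, which limits array calls, was not measured here.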

Other observations

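The tests in this part were chosen only after the results were seen. In LKO livers the ductular, matrix and macrophage levels were lower on HFC than on LFnC. The mean ductular level of 6 LKO mice was 1.00 (SD 0.28) on LFnC and -0.32 (SD 0.12) on HFC, the matrix level 0.67 (SD 0.21) and -0.26 (SD 0.12), and the macrophage level 0.49 (SD 0.22) and -0.17 (SD 0.03). In LWT mice the mean matrix level was -0.36 (SD 0.08) on LFnC and 0.25 (SD 0.64) on HFC, the macrophage level -0.32 (SD 0.22) and 0.30 (SD 0.33), and the ductular level -0.28 (SD 0.21) and -0.01 (SD 0.52). Without male LWT replicates 1 and 2 the 4 other LWT mice on HFC had means of -0.09 (SD 0.30), 0.17 (SD 0.34) and -0.28 (SD 0.29).

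These lists were picked from 28 after their levels were seen, so each was held against the largest t over all 28 lists in each of the 462 splits of 12 mice into 6 and 6. In LKO the share of splits with a t as large was 0.0022 for the ductular and matrix lists, the smallest share possible, and 0.0065 for the macrophage list. In LWT it was 0.98, 0.44 and 0.076. The splits ignored sex, and the 28 lists include sex-biased genes, so these shares may be too high. Whether LKO and LWT differed in this comparison was not tested. Chance is thus argued against in LKO as far as the choice among the lists goes, while the choice of this comparison after seeing the data is not allowed for. The cause of the lower levels was not tested. These diets differ in fat, cholesterol and supplier, which cannot be separated in this comparison.

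The changes in LKO livers on LFnC resembled those in LWT livers given cholesterol. Both comparisons called 576 genes, 474 higher in both, 59 lower in both and 43 in opposite directions, where chance would give 97.7, 44.1 and 165, and the changes correlated at 0.56 across genes, which are not independent replicates. The likeness may rest on male LWT replicates 1 and 2 on HFC, since without them the correlation was 0.17 and 33 genes were shared, 12 higher in both, 1 lower in both and 20 in opposite directions, where chance would give 3.7, 5.19 and 8.84.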
